A study of Mus musculus with 6 samples.

How the data were processed

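Thoracic aorta of C57Bl/6 mice was profiled on 6 Illumina expression BeadChips: 1 array each of saline-infused wild-type (WT) mice and mice with a CaMKII inhibitor peptide in smooth muscle (TG), and 2 arrays each of Ang-II-infused WT and TG mice. Per the labels' protocols, total RNA was extracted with Trizol from 5 mice per group, pooled, and labelled as biotin-aRNA with a TargetAmp-Nano kit. The labels name GenomeStudio 2011.1 and limma 3.22.1 without giving their roles. Per the file headers, the deposited signal columns hold the mean intensity of the beads of a probe on 1 array, with its standard error over the beads and the number of beads (a median of 41 to 43 per probe and array). These intensities are on a linear scale and were not normalized, as their medians differ between arrays. The deposited detection p-value columns, per the file headers, hold each probe's detection p, in steps of 1 in 936. The deposited value table holds log2 values with the same median (4.84) on each array, and the method is not given in the sources used here. All 271686 of its values equal, within 1e-08, those computed below from the intensities. The deposited columns pair with the labelled samples by name, and the value table follows the same order of samples by its values.

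Choices of comparisons, tests, gene lists, named genes and alternatives were made before the data were examined, except where stated. Intensities were background corrected with the detection p-values and quantile normalized on the log2 scale by neqc in limma 3.58.1 (R 4.3.3) with an offset of 16. Probes with a detection p under 0.01 on at least 2 of the 6 arrays were kept (16749 of 45281). Gene symbols came from the platform's probe annotation, brought to current symbols through the RefSeq gene table of assembly GRCm38.p6 by gene identifier (34807 probes found). That table served only for names and for which genes neighbour each other. The array holds 34885 probes with 1 symbol, 18 with several and 10378 with none here, and 14523 of the probes kept had 1 symbol. For gene values and lists each of 9837 genes was represented by its probe with the highest mean over the 6 arrays.

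A model with 4 group means was fitted to all 6 arrays in limma, with 2 residual degrees of freedom, 3.75 prior degrees of freedom and a prior SD of 0.15 (eBayes, constant prior). The comparisons were Ang-II against saline in WT, in TG and averaged over both, TG against WT under Ang-II and under saline, and the interaction (TG response minus WT response). A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over the probes of a comparison. The median SE of a log2 difference was 0.18 for each genotype's Ang-II response, 0.13 for their average, 0.15 for TG against WT under Ang-II, 0.21 under saline and 0.25 for the interaction. The median log2 difference of all probes lay between -0.06 and 0.00 in each comparison. For a gene not well above background in the dimmer group, a lower bound of the fold was computed from the brighter group's mean and the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest detected value (5.54 to 5.69 over the arrays). The genes named are the 12 largest rises and 12 largest falls that passed per comparison (moved the same way on both Ang-II arrays in an Ang-II comparison, on all 4 in the average), up to 4 members per list that passed or 2 where none did, and 10 fixed genes. RIKEN, Gm, LOC and accession names were left out. Of the fixed genes, Ddx3y had no named probe.

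Lists of markers and pathways (26 with at least 5 measured genes) were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over their list alone. List medians were computed again with genes not well above background at their bound. The similarity of both Ang-II responses was described by Pearson r and a total-least-squares slope. Fold changes of both genotypes share no array.

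The alternatives were quantile normalization of log2 intensities without background correction, an offset of 50, the deposited value table, no detection filter, detection on all 6 arrays, probes averaged per gene, array weights, and a trended robust prior. Others were each Ang-II array left out in turn, a replicate block, only the 4 Ang-II arrays, an additive model, and other probes of a gene. A refit without the genes of the heart muscle, fat cell and red cell lists was chosen after seeing the data, as were 3 lists given among the further observations. Tested on simulated data with 100 changed probes per size, a change of 2 on the log2 scale was called for 85% of probes in WT, 89% in TG, 99% in the average, 91% between genotypes under Ang-II, 71% under saline and 0% in the interaction. A change of 1 was called for 7%, 7%, 60%, 36%, 0% and 0%, in the same order. The share of false calls was 9.80%, 8.57%, 4.22%, 1.55%, 5.33% and 0%. In the data more probes had an unadjusted p under 0.05 (4644 in WT, 2314 in the interaction) than were changed here. The adjusted threshold is then looser, so these shares do not give the sensitivity in the data. Among 26 simulated lists in WT, a shift of 0.5 put into the matrix list gave adjusted p = 8.73e-21 with the preset and 0.231 with the estimated correlation, and 0 of the other 25 lists were called. As the simulated genes varied independently, the 0 says nothing of false calls where members move together, nor does the 0.231 come from correlated members. In simulated responses with slopes of 1 and 0.5 the slopes found were 0.999 and 0.496.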

Results

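Gene expression in the thoracic aorta of mice was measured on 6 Illumina bead arrays that carry 45281 probes. Transgenic mice (TG) expressed CaMKIIN, a peptide that inhibits the calcium/calmodulin-dependent kinase CaMKII, in smooth muscle, and wild-type littermates (WT) did not. At 12 weeks of age, per the labels, mice received angiotensin II (Ang-II) at 1.25 ug/kg/min or 0.9% saline through implanted pumps for 14 days, and RNA of the 5 mice in a group was pooled. Ang-II is a vasoconstrictor hormone, and the design asks how it changes transcripts of the aorta and whether inhibition of CaMKII in smooth muscle alters that response. There was 1 array each for WT saline and TG saline and 2 each for WT Ang-II and TG Ang-II. The sample titles call the 2 Ang-II arrays of a genotype biological replicates, while the protocols speak of RNA pooled per group. Nothing in the labels says which mice entered each array of a group, so p-values measure only the spread between these arrays, which may be technical, and each lone saline array is assumed to vary like the Ang-II arrays. The number of arrays limits the precision of every value. The median raw signal was 131 on the WT saline array and between 110.0 and 118 on the other arrays, and between 15393 and 16075 probes (34.0% to 35.5%) were detected. The limma test covered 16749 probes. Gene values below are for 9837 genes with 1 probe each, as the log2 difference ± its standard error (SE). Each Ang-II response that passed within a genotype and is given below went the same way on both Ang-II arrays of the genotype. Where a gene was not well above background in the dimmer group, the fold is a lower bound, written as at least N-fold.

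The 2 arrays of a group correlated across probes with r = 0.991 for WT Ang-II and 0.990 for TG Ang-II, with SDs of their differences of 0.28 and 0.30 on the log2 scale. Probes are not independent replicates. The squared difference between the 2 arrays had a median of 2.13 times the variance expected from the beads for WT Ang-II and 1.88 times for TG Ang-II, which does not tell separate mice from repeated hybridization of 1 pool. The first principal component (42.9% of the variance) parted the saline arrays (-35.8 for WT and -42.0 for TG) from the Ang-II arrays (10.5 to 27.8), and the second (32.5%) parted the WT Ang-II arrays (27.2 and 22.1) from the TG Ang-II arrays (-32.7 and -32.9). Camk2n1, which encodes an endogenous CaMKII inhibitor protein, had normalized log2 signals of 11.70 in WT saline, 11.51 in TG saline, 11.47 and 11.66 in WT Ang-II and 11.53 and 11.60 in TG Ang-II. Camk2n2, which encodes the other such protein, lay between 8.69 and 8.93 on the 6 arrays. Whether the transgene carries the sequence of either probe is not given in the sources used here, so these probes check neither the labels nor the transgene. Among the genes of the kinase itself, Camk2a was not detected, and Camk2b, Camk2d and Camk2g, each by its brightest probe, did not pass in any of the 6 comparisons. Between TG and WT under Ang-II they differed by 0.23 ± 0.14, adjusted p = 0.411, by 0.00 ± 0.13, adjusted p = 0.988 and by 0.22 ± 0.13, adjusted p = 0.383. The fall of Camk2g in WT (-0.62 ± 0.16, adjusted p = 0.0653) and in the average (-0.38 ± 0.11, adjusted p = 0.0673) passed with quantile normalization without background correction (adjusted p = 0.00534 and 0.00919), an offset of 50 (0.0263 and 0.0315), detection on all 6 arrays (0.0393 and 0.0443) and a trended robust prior (0.00229 and 0.00486). Another probe of Camk2d rose by 0.97 in WT (adjusted p = 0.0426) and 0.62 in the average (adjusted p = 0.0351). Agtr1a, the main vascular receptor of Ang-II in mice, was 6.07 in WT saline, 7.77 in TG saline, 6.69 and 6.53 in WT Ang-II and 7.57 and 8.03 in TG Ang-II. Agtr1b and the 4 probes of Xist, the transcript that silences an X chromosome in females, were not detected at the threshold on any array.

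In WT aorta, Ang-II raised transcripts of extracellular matrix, macrophages and dividing cells (2 Ang-II arrays against 1 saline array). Cthrc1, a secreted protein of fibroblasts in injured arteries, rose at least 8.57-fold (adjusted p = 0.000921), and Cemip, which takes part in the breakdown of hyaluronan, rose at least 6.16-fold (adjusted p = 0.00118). C1qtnf3, a secreted C1q/TNF-related protein, rose 10.8-fold (log2 3.43 ± 0.17, adjusted p = 0.00262), Adamts12, a secreted metalloprotease, rose 6.38-fold (log2 2.67 ± 0.17, adjusted p = 0.00358), and Ddah1, which degrades the nitric oxide synthase inhibitor asymmetric dimethylarginine, rose 7.59-fold (log2 2.93 ± 0.15, adjusted p = 0.00267). Of 30 measured collagens and matrix proteins, 14 rose, 0 fell and 16 did not pass (19 rose and 0 fell when adjusted over the list alone). The matrix median was 0.64 (camera adjusted p = 2.59e-10, adjusted p = 0.154 with an estimated correlation). Among them Col1a1 and Col8a1, chains of type I and type VIII collagen, rose 3.52-fold (log2 1.82 ± 0.16, adjusted p = 0.00503) and 3.21-fold (log2 1.68 ± 0.15, adjusted p = 0.00521). Of 21 matrix proteases and inhibitors, 4 rose, 1 fell and 16 did not pass (5 rose and 2 fell when adjusted over the list alone). The protease median was 0.32 (camera adjusted p = 0.00862, adjusted p = 0.283 with an estimated correlation). Ctsk, the collagen-degrading protease cathepsin K, rose 4.65-fold (log2 2.22 ± 0.15, adjusted p = 0.00391). Of 20 macrophage and monocyte markers, 16 rose, 0 fell and 4 did not pass (19 rose and 0 fell when adjusted over the list alone). The macrophage median was 1.14 (camera adjusted p = 1.36e-14, adjusted p = 0.154 with an estimated correlation). H2-Ab1 and Cd74, which belong to antigen presentation by MHC class II and are also expressed in other antigen-presenting cells, rose 4.13-fold (log2 2.05 ± 0.16, adjusted p = 0.00433) and 3.31-fold (log2 1.73 ± 0.15, adjusted p = 0.00516), and Ms4a7, a membrane protein of macrophages, rose 3.52-fold (log2 1.82 ± 0.16, adjusted p = 0.00503). Of 20 chemokines and cytokines, 6 rose, 0 fell and 14 did not pass (9 rose and 0 fell when adjusted over the list alone). The chemokine median was 0.65 (camera adjusted p = 0.000687, adjusted p = 0.239 with an estimated correlation), and 0.51 with 4 members not well above background at their bound. Ccl8, a chemokine that attracts monocytes, rose 6.45-fold (log2 2.69 ± 0.22, adjusted p = 0.00486). Of 14 adventitial fibroblast markers, 3 rose, 0 fell and 11 did not pass (6 rose and 0 fell when adjusted over the list alone). The fibroblast median was 0.51 (camera adjusted p = 0.000176, adjusted p = 0.160 with an estimated correlation). Of 17 cell cycle genes, 6 rose, 0 fell and 11 did not pass (8 rose and 1 fell when adjusted over the list alone). The cell cycle median was 0.53 (camera adjusted p = 0.000404, adjusted p = 0.160 with an estimated correlation). Plk1, a mitotic kinase, rose 3.19-fold (log2 1.67 ± 0.15, adjusted p = 0.00522). The cell cycle call ended when probes had to be detected on all 6 arrays (adjusted p = 0.473). Of 18 oxidant and antioxidant enzymes, 5 rose, 1 fell and 12 did not pass (5 rose and 1 fell when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.125). Ncf4 and Rac2, components of the phagocyte NADPH oxidase, rose at least 4.03-fold (adjusted p = 0.00405) and at least 1.31-fold (adjusted p = 0.0183). On the same 2 arrays the medians of the general adipocyte and erythroid lists were 1.41 and 1.90 above the saline array, and that of the striated muscle list was -0.64.

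**Figure D1:**
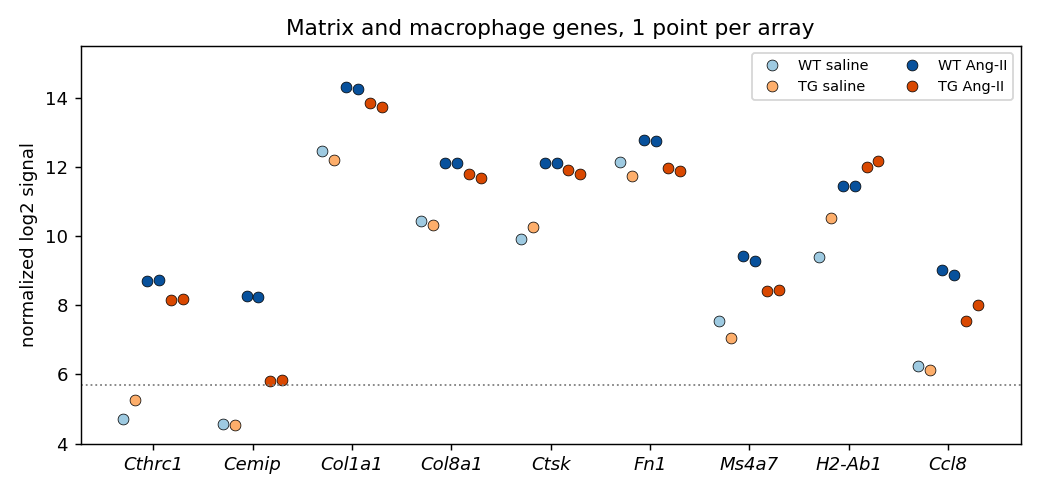
Normalized log2 signal of 9 matrix, macrophage and related genes on each of the 6 arrays, with 1 point per array and a dotted line at 5.69, the highest over the arrays of the lowest value among detected probes. Cthrc1 and Cemip lay at 4.7 and 4.6 in WT saline, below the dotted line, and Cthrc1 rose to a mean of 8.7 in WT Ang-II and 8.2 in TG Ang-II, while Cemip rose to 8.3 and 5.8.

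Contractile genes of smooth muscle fell in WT aorta after Ang-II. Of 19 measured members, 0 rose, 6 fell and 13 did not pass (1 rose and 12 fell when adjusted over the list alone). The contractile gene median was -0.58 (camera adjusted p = 1.16e-05, adjusted p = 0.154 with an estimated correlation). Ppp1r14a, an inhibitor of smooth muscle myosin phosphatase, fell 2.24-fold (log2 -1.16 ± 0.15, adjusted p = 0.0121), and Tagln, an actin-binding protein of smooth muscle, fell 2.09-fold (log2 -1.06 ± 0.15, adjusted p = 0.0147). Fat cell and red cell transcripts rose on the same arrays. Of 10 brown adipocyte markers, 7 rose, 0 fell and 3 did not pass (7 rose and 1 fell when adjusted over the list alone). The brown adipocyte median was 1.62 (camera adjusted p = 5.74e-07, adjusted p = 0.154 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, rose 6.77-fold (log2 2.76 ± 0.16, adjusted p = 0.00337). Of 14 general adipocyte markers, 9 rose, 0 fell and 5 did not pass (11 rose and 0 fell when adjusted over the list alone). The adipocyte median was 1.41 (camera adjusted p = 5.49e-09, adjusted p = 0.154 with an estimated correlation). Scd1, a stearoyl-CoA desaturase, rose 3.23-fold (log2 1.69 ± 0.16, adjusted p = 0.00531). Of 7 erythroid markers, 5 rose, 0 fell and 2 did not pass (6 rose and 0 fell when adjusted over the list alone). The erythroid median was 1.90 (camera adjusted p = 3.29e-07, adjusted p = 0.217 with an estimated correlation). Hbb-bt, a beta globin, rose 4.06-fold (log2 2.02 ± 0.16, adjusted p = 0.00422). Of 11 striated muscle markers, 1 rose, 4 fell and 6 did not pass (1 rose and 9 fell when adjusted over the list alone). The striated muscle median was -0.64 (camera adjusted p = 1.89e-05, adjusted p = 0.154 with an estimated correlation), and -0.58 with 6 members at their bound. Mb, which encodes myoglobin, fell 4.60-fold (log2 -2.20 ± 0.15, adjusted p = 0.00391), and Nppa, which encodes atrial natriuretic peptide, fell at least 4.31-fold (adjusted p = 0.00262). Sspn, a member of the dystrophin-associated complex, fell at least 84.7-fold (adjusted p = 0.000289), and Me1, the cytosolic malic enzyme, fell at least 13.4-fold (adjusted p = 0.000916). Each of these falls rests on a single probe, as no other probe of the gene was kept. Of 12 circadian clock genes, 0 rose, 2 fell and 10 did not pass (1 rose and 6 fell when adjusted over the list alone). The clock median was -0.51 (camera adjusted p = 0.00455, adjusted p = 0.283 with an estimated correlation). Npas2, a clock transcription factor, fell at least 2.51-fold (adjusted p = 0.00500). Of 12 heat shock genes, 3 rose, 0 fell and 9 did not pass (3 rose and 0 fell when adjusted over the list alone). The heat shock median was 0.35 (camera adjusted p = 0.00862, adjusted p = 0.390 with an estimated correlation). Hspa1a, an inducible HSP70, rose 2.72-fold (log2 1.44 ± 0.15, adjusted p = 0.00819). Of 21 respiratory chain genes, 0 rose and 0 fell by limma, where 10 were higher and 0 lower at an unadjusted p under 0.05, and the list passed as a whole (median 0.45, camera adjusted p = 4.58e-05, adjusted p = 0.154 with an estimated correlation, fry adjusted p = 0.00499). Over all probes 1063 rose and 455 fell (limma adjusted p under 0.05), 735 and 364 genes by at least 1 of their probes, as in the counts of genes that follow. Quantile normalization without background correction gave 2931 calls (55.9% of them rises, against 70.0%), an offset of 50 gave 2323, a trended robust prior 3015 and no detection filter 781. Leaving out WT Ang-II array 1 or 2 gave 252 or 209 calls and ended those of Ppp1r14a (adjusted p = 0.0672 or 0.0704), Tagln (0.0751 or 0.0819) and Hspa1a (0.0544 or 0.0577).

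In TG aorta, Ang-II also raised matrix and macrophage transcripts, and most of the largest rises were of transcripts abundant in heart muscle (2 Ang-II arrays against 1 saline array). Of 30 collagens and matrix proteins, 12 rose, 0 fell and 18 did not pass (18 rose and 0 fell when adjusted over the list alone). The matrix median was 0.61 (camera adjusted p = 8.03e-12, adjusted p = 0.287 with an estimated correlation). Col1a1 rose 3.03-fold (log2 1.60 ± 0.16, adjusted p = 0.00805), Col8a1 2.66-fold (log2 1.41 ± 0.15, adjusted p = 0.00936) and Fmod, a collagen-binding proteoglycan, 3.04-fold (log2 1.61 ± 0.15, adjusted p = 0.00749). Of 20 macrophage and monocyte markers, 15 rose, 0 fell and 5 did not pass (20 rose and 0 fell when adjusted over the list alone). The macrophage median was 1.01 (camera adjusted p = 3.86e-15, adjusted p = 0.287 with an estimated correlation). H2-Ab1 rose 2.94-fold (log2 1.56 ± 0.16, adjusted p = 0.00926) and Fcgr3, an Fc receptor for immunoglobulin G, 2.57-fold (log2 1.36 ± 0.16, adjusted p = 0.00987). Of 14 fibroblast markers, 2 rose, 0 fell and 12 did not pass (4 rose and 0 fell when adjusted over the list alone). The fibroblast median was 0.30 (camera adjusted p = 0.00359, adjusted p = 0.359 with an estimated correlation). Of 21 matrix proteases and inhibitors, 4 rose, 1 fell and 16 did not pass (4 rose and 1 fell when adjusted over the list alone). The protease median was 0.16 (camera adjusted p = 0.0212, adjusted p = 0.417 with an estimated correlation). Ctsk rose 3.03-fold (log2 1.60 ± 0.15, adjusted p = 0.00805) and Timp4, an inhibitor of metalloproteases, fell 3.54-fold (log2 -1.82 ± 0.15, adjusted p = 0.00603). The call of this list ended without TG Ang-II array 2 (adjusted p = 0.0813). Of 20 chemokines and cytokines, 3 rose, 1 fell and 16 did not pass (4 rose and 1 fell when adjusted over the list alone). The chemokine median was 0.27 (camera adjusted p = 0.0212, adjusted p = 0.421 with an estimated correlation). Ccl21a, a chemokine for lymphocytes and dendritic cells, rose 2.86-fold (log2 1.52 ± 0.17, adjusted p = 0.00936). The chemokine call ended without TG Ang-II array 1 (adjusted p = 0.0670). Of 18 immediate-early genes, 0 rose, 4 fell and 14 did not pass (0 rose and 6 fell when adjusted over the list alone). The immediate-early median was -0.20 (camera adjusted p = 0.0212, adjusted p = 0.389 with an estimated correlation). The transcription factor genes Fos and Atf3 fell 3.58-fold (log2 -1.84 ± 0.15, adjusted p = 0.00603) and 2.80-fold (log2 -1.48 ± 0.18, adjusted p = 0.0111). Of 18 unfolded protein response genes, 4 rose, 0 fell and 14 did not pass (5 rose and 0 fell when adjusted over the list alone). The unfolded protein response median was 0.24 (camera adjusted p = 0.00288, adjusted p = 0.359 with an estimated correlation). Pdia4, a protein disulfide isomerase of the endoplasmic reticulum, rose 3.16-fold (log2 1.66 ± 0.16, adjusted p = 0.00805). Of 10 brown adipocyte markers, 2 rose, 0 fell and 8 did not pass (4 rose and 0 fell when adjusted over the list alone). The brown adipocyte median was 0.31 (camera adjusted p = 0.0212, adjusted p = 0.389 with an estimated correlation). The 2 that rose were Cox7a1, a subunit of cytochrome c oxidase in fat and muscle (0.77 ± 0.15, adjusted p = 0.0428), and Fabp3, a fatty acid binding protein that is also abundant in heart muscle (1.44 ± 0.16, adjusted p = 0.00936). That list's call ended without the detection filter (adjusted p = 0.0703), and that of Cox7a1 ended there (0.0690) and when 1 array was left out (0.107 without TG Ang-II array 1, 0.0820 without TG Ang-II array 2, 0.0855 and 0.0870 without WT Ang-II array 1 and 2).

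Of 11 striated muscle markers, 6 rose, 0 fell and 5 did not pass (6 rose and 0 fell when adjusted over the list alone) in TG after Ang-II. The striated muscle median was 1.59 (camera adjusted p = 6.52e-07, adjusted p = 0.287 with an estimated correlation), and 0.57 with 3 members at their bound. The list's call ended when probes had to be detected on all 6 arrays (adjusted p = 0.0782). Of the genes with the largest rises, Myl2 and Myl3, the ventricular myosin light chains, rose 28.0-fold (log2 4.81 ± 0.18, adjusted p = 0.000561) and 20.7-fold (log2 4.37 ± 0.23, adjusted p = 0.00131), Mb rose 18.5-fold (log2 4.21 ± 0.15, adjusted p = 0.000561) and Nppa at least 11.6-fold (adjusted p = 0.000561). Pln, a regulator of the calcium pump of the sarcoplasmic reticulum in heart and smooth muscle, rose 6.58-fold (log2 2.72 ± 0.17, adjusted p = 0.00273). Hnrnpl, an RNA-binding protein, rose 45.2-fold (log2 5.50 ± 0.15, adjusted p = 0.000561); its signal was 6.23 on the TG saline array, 11.33 on the WT saline array and 11.91 and 11.73 as means of the Ang-II groups. Of 19 contractile genes of smooth muscle, 1 rose, 1 fell and 17 did not pass (1 rose and 1 fell when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.183). Myocd, a coactivator of smooth and heart muscle genes, rose 2.82-fold (log2 1.49 ± 0.17, adjusted p = 0.00944). Among the falls, Scgb1a1, the secretoglobin of airway club cells, fell 5.74-fold (log2 -2.52 ± 0.22, adjusted p = 0.00656), Klk10, a kallikrein-related peptidase, fell 4.21-fold (log2 -2.07 ± 0.16, adjusted p = 0.00515), and Serpina1d, an alpha-1 antitrypsin gene with near-identical paralogs that its probe may also measure, fell 3.76-fold (log2 -1.91 ± 0.15, adjusted p = 0.00577). General adipocyte and erythroid markers did not pass as lists (camera adjusted p = 0.351 for each). Over all probes 978 rose and 290 fell, 685 and 238 genes. The count of 1268 calls was 2233 with quantile normalization without background correction (63.7% rises, against 77.1%), 2303 with a trended robust prior, 604 without the detection filter and 754 with probes averaged per gene. It was 738 and 794 without TG Ang-II array 1 and 2, and 681 and 639 without WT Ang-II array 1 and 2.

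Averaged over both genotypes, Ang-II raised matrix and macrophage transcripts (4 Ang-II arrays against 2 saline arrays). Fat cell transcripts rose and contractile genes fell in the average, while in TG alone the lists of general adipocyte markers (median 0.06, camera adjusted p = 0.351) and contractile genes (-0.23, 0.183) did not pass. C1qtnf3 rose 9.21-fold (log2 3.20 ± 0.12, adjusted p = 0.000639), Ddah1 6.34-fold (log2 2.67 ± 0.11, adjusted p = 0.000819), Angptl1, a secreted angiopoietin-like protein, 4.65-fold (log2 2.22 ± 0.11, adjusted p = 0.00158), and Depp1, an autophagy regulator, 4.36-fold (log2 2.12 ± 0.11, adjusted p = 0.00136), each in the same direction on all 4 Ang-II arrays. Of 30 collagens and matrix proteins, 17 rose, 0 fell and 13 did not pass (22 rose and 0 fell when adjusted over the list alone). The matrix median was 0.64 (camera adjusted p = 3.14e-12, adjusted p = 0.243 with an estimated correlation). Of 20 macrophage and monocyte markers, 19 rose, 0 fell and 1 did not pass (20 rose and 0 fell when adjusted over the list alone). The macrophage median was 1.05 (camera adjusted p = 1.89e-15, adjusted p = 0.243 with an estimated correlation). H2-Ab1 rose 3.49-fold (log2 1.80 ± 0.12, adjusted p = 0.00257). Of 21 matrix proteases and inhibitors, 7 rose, 2 fell and 12 did not pass (8 rose and 2 fell when adjusted over the list alone). The protease median was 0.22 (camera adjusted p = 0.00701, adjusted p = 0.243 with an estimated correlation). Mmp2, a gelatinase, rose 2.27-fold (log2 1.18 ± 0.11, adjusted p = 0.00368) and Timp4 fell 2.30-fold (log2 -1.20 ± 0.11, adjusted p = 0.00341). Of 20 chemokines and cytokines, 6 rose, 1 fell and 13 did not pass (14 rose and 2 fell when adjusted over the list alone). The chemokine median was 0.53 (camera adjusted p = 0.000181, adjusted p = 0.243 with an estimated correlation). Cxcl12, a chemokine of stromal cells, rose 1.75-fold (log2 0.80 ± 0.11, adjusted p = 0.00921). Of 14 fibroblast markers, 5 rose, 0 fell and 9 did not pass (8 rose and 0 fell when adjusted over the list alone). The fibroblast median was 0.37 (camera adjusted p = 0.000181, adjusted p = 0.243 with an estimated correlation). Of 17 cell cycle genes, 8 rose, 1 fell and 8 did not pass (9 rose and 1 fell when adjusted over the list alone). The cell cycle median was 0.68 (camera adjusted p = 0.00701, adjusted p = 0.243 with an estimated correlation); with probes detected on all 6 arrays that list's median was -0.11. Of 9 genes of the renin-angiotensin and endothelin systems, 3 rose, 0 fell and 6 did not pass (4 rose and 1 fell when adjusted over the list alone). The endothelin and angiotensin median was 0.28 (camera adjusted p = 0.0314, adjusted p = 0.243 with an estimated correlation). Ednrb, the endothelin receptor B, rose 2.83-fold (adjusted p = 0.00309). That list's call ended with probes averaged per gene (adjusted p = 0.0926). Of 18 unfolded protein response genes, 4 rose, 0 fell and 14 did not pass (4 rose and 0 fell when adjusted over the list alone). The unfolded protein response median was 0.23 (camera adjusted p = 0.0112, adjusted p = 0.243 with an estimated correlation). Asns, the asparagine synthetase, rose 1.96-fold (log2 0.97 ± 0.13, adjusted p = 0.00814). Of 21 respiratory chain genes, 0 rose and 0 fell by limma (3 higher and 0 lower at an unadjusted p under 0.05), while the list passed as a whole (median 0.20, camera adjusted p = 0.0254, adjusted p = 0.243 with an estimated correlation, fry adjusted p = 0.0134), but not with probes averaged per gene (adjusted p = 0.0676). Of 10 brown and 14 general adipocyte markers, 8 and 9 rose and 0 fell (8 and 10 rose and 1 and 1 fell when adjusted over the list alone), with medians of 1.02 and 0.78 and camera adjusted p = 1.12e-05 and 2.11e-05. Adjusted p was 0.243 and 0.243 for them with an estimated correlation. Of 7 erythroid markers, 5 rose, 0 fell and 2 did not pass (5 rose and 0 fell when adjusted over the list alone). The erythroid median was 1.05 (camera adjusted p = 6.33e-05, adjusted p = 0.243 with an estimated correlation). Striated muscle markers, which as a list rose in TG and fell in WT, also passed in the average. Of 11 of them, 7 rose, 2 fell and 2 did not pass (7 rose and 2 fell when adjusted over the list alone). The striated muscle median was 0.73 (camera adjusted p = 0.0311, adjusted p = 0.243 with an estimated correlation). The striated muscle call ended without the detection filter (adjusted p = 0.126) and without TG Ang-II array 1 (adjusted p = 0.0564), and with probes detected on all 6 arrays the median was -0.17.

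Of 19 contractile genes of smooth muscle, 1 rose, 9 fell and 9 did not pass (1 rose and 13 fell when adjusted over the list alone) in the average. The contractile gene median was -0.42 (camera adjusted p = 0.000853, adjusted p = 0.243 with an estimated correlation). Ppp1r14a fell 2.05-fold (log2 -1.04 ± 0.11, adjusted p = 0.00405) and Myocd rose 2.07-fold (log2 1.05 ± 0.12, adjusted p = 0.00505). The other 12 lists did not pass in the average. Of 18 immediate-early genes, 1 rose, 4 fell and 13 did not pass (1 rose and 5 fell when adjusted over the list alone) (camera adjusted p = 0.125), where Fosb, a subunit of the transcription factor AP-1, fell 2.25-fold (log2 -1.17 ± 0.14, adjusted p = 0.00561). Camera adjusted p was 0.0722 for circadian clock genes (0 rose, 4 fell), 0.125 for oxidant and antioxidant enzymes (4 rose, 1 fell), 0.142 for heat shock genes (2 rose, 1 fell) and 0.201 for TGF-beta ligands and targets (2 rose, 2 fell). It was 0.813 for CaMKII and calcium handling genes (4 rose, 1 fell), 0.342 for interferon-stimulated genes (1 rose, 0 fell), 0.358 for osteochondrogenic genes (1 rose, 1 fell) and 0.727 for NF-kappaB and adhesion genes (0 rose and 0 fell by limma, 4 higher and 1 lower at an unadjusted p under 0.05, fry adjusted p = 0.307). Among markers of other cells, camera adjusted p was 0.342 for endothelium (2 rose, 4 fell), 0.625 for lymphocytes (2 rose, 1 fell) and 0.885 for Schwann cells and nerve (0 rose and 0 fell by limma, 1 higher and 1 lower at an unadjusted p under 0.05, fry adjusted p = 0.0181). Within the endothelial list Nos3, the endothelial nitric oxide synthase, fell 1.67-fold (log2 -0.74 ± 0.11, adjusted p = 0.0121) and Robo4, an endothelial guidance receptor, rose 2.31-fold (log2 1.20 ± 0.11, adjusted p = 0.00368). Of 12 neutrophil markers 4 were measured, and that list was not tested. Over all probes 1945 rose and 1264 fell, 1313 and 981 genes. Quantile normalization without background correction gave 2460 rises and 2299 falls (51.7% rises, against 60.6%). The count of 3209 calls was 2106 without the detection filter, 2113 with probes averaged per gene, 1838 in an additive model, and 1724 and 1555 without WT Ang-II array 1 and 2.

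The responses of both genotypes, which share no array, correlated across the 16749 probes with r = 0.46 and a total-least-squares slope of TG on WT of 0.96, with a jackknife SD of 0.07 from leaving out each Ang-II array in turn (no saline array was left out). Over the 3209 probes called in the average, r was 0.56 and the slope 0.94, a choice of probes that favours responses of the same sign. Genes are not independent replicates, and no test was made of the slope. It was 0.87 with probes detected on all 6 arrays and 0.88 with probes averaged per gene. Of the probes called in each genotype, 409 rose in both (62.1 would be shared by independent calls), 55 fell in both (7.88), 5 rose in WT and fell in TG (18.4), and 25 fell in WT and rose in TG (26.6). Both sets of calls use the same estimate of each probe's spread, so the numbers for independent calls are only a rough reference.

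**Figure D2:**
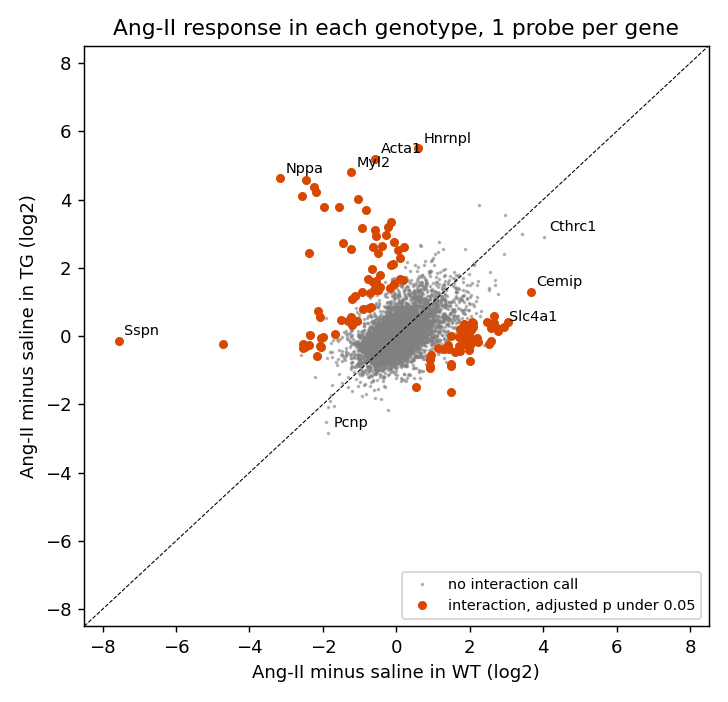
Log2 difference between Ang-II and saline in WT (x axis) against that in TG (y axis), with 1 point per gene, orange points for genes whose interaction of genotype and Ang-II had a limma adjusted p under 0.05, and a dashed line where both responses are equal. Points gather around 0 (r = 0.46 over all probes), and heart muscle genes such as Myl2 and Mb lie above it, where Mb fell by 2.20 in WT and rose by 4.21 in TG.

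Under Ang-II, TG aorta differed from WT aorta in transcripts abundant in heart muscle and in markers of fat cells, red cells and the heat shock response (2 arrays against 2). Myl2 (at least 124-fold, adjusted p = 3.26e-05), Myl3 (at least 155-fold, adjusted p = 5.23e-05), Csrp3, a muscle LIM protein (at least 44.3-fold, adjusted p = 4.75e-05), and Mb (log2 6.70 ± 0.13, adjusted p = 3.26e-05) were higher in TG. Of 11 striated muscle markers, 8 were higher, 0 were lower and 3 did not pass (8 higher and 0 lower when adjusted over the list alone). The striated muscle median was 1.70 (camera adjusted p = 7.54e-11, adjusted p = 0.283 with an estimated correlation), and 0.73 with 6 members at their bound. In the additive model, which averages the genotype effect over saline and Ang-II, the calls of Myl2, Myl3, Csrp3 and Mb ended (adjusted p = 0.0703, 0.0955, 0.184 and 0.138). Of 10 brown adipocyte markers, 1 was higher, 2 were lower and 7 did not pass (1 higher and 7 lower when adjusted over the list alone). The brown adipocyte median was -0.58 (camera adjusted p = 0.000436, adjusted p = 0.283 with an estimated correlation). The 1 that was higher was Fabp3, which heart muscle also expresses (1.11 ± 0.13, adjusted p = 0.00976), and Ucp1 was lower (-1.07 ± 0.13, adjusted p = 0.0113). Of 14 general adipocyte markers, 0 were higher, 5 were lower and 9 did not pass (0 higher and 9 lower when adjusted over the list alone). The adipocyte median was -0.57 (camera adjusted p = 9.14e-07, adjusted p = 0.283 with an estimated correlation). Lep, the adipocyte hormone leptin, was lower (-1.09 ± 0.12, adjusted p = 0.00905). Of 7 erythroid markers, 1 was higher, 5 were lower and 1 did not pass (1 higher and 5 lower when adjusted over the list alone). The erythroid median was -0.89 (camera adjusted p = 0.00133, adjusted p = 0.323 with an estimated correlation). Slc4a1, the red cell anion exchanger, was lower (at least 5.34-fold, adjusted p = 0.000598), and Hbb-b2 was the 1 that was higher (log2 2.22 ± 0.36, adjusted p = 0.0292). The Hbb-b2 probe read 9.40 on the TG and 5.50 on the WT saline array. It is among the 45 probes, described further below, that parted all TG from all WT arrays. Of 12 heat shock genes, 0 were higher, 4 were lower and 8 did not pass (0 higher and 6 lower when adjusted over the list alone). The heat shock median was -0.41 (camera adjusted p = 5.39e-05, adjusted p = 0.283 with an estimated correlation). The chaperone genes Hspa1a and Dnajb1 were lower (log2 -1.64 ± 0.13, adjusted p = 0.00276, and log2 -1.78 ± 0.12, adjusted p = 0.00206). Of 17 cell cycle genes, 0 were higher, 4 were lower and 13 did not pass (0 higher and 7 lower when adjusted over the list alone). The cell cycle median was -0.35 (camera adjusted p = 0.000458, adjusted p = 0.283 with an estimated correlation). Plk1 was lower (log2 -1.64 ± 0.12, adjusted p = 0.00269). The cell cycle call ended with probes detected on all 6 arrays (adjusted p = 0.324). The calls of Ucp1 and Lep ended without WT Ang-II array 1 (adjusted p = 0.0776 and 0.0804) or 2 (0.0895 and 0.0768) and in the additive model (0.881 and 0.209). That of Fabp3 ended without WT Ang-II array 1 (adjusted p = 0.0895) or 2 (0.0766) and in the additive model (0.209). That of Hbb-b2 ended without WT Ang-II array 1 (0.183) or 2 (0.119) and without the detection filter (0.106). In the additive model adjusted p was 0.135 for Slc4a1, 0.218 for Hspa1a, 0.164 for Dnajb1 and 0.0703 for Plk1.

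**Figure D3:**
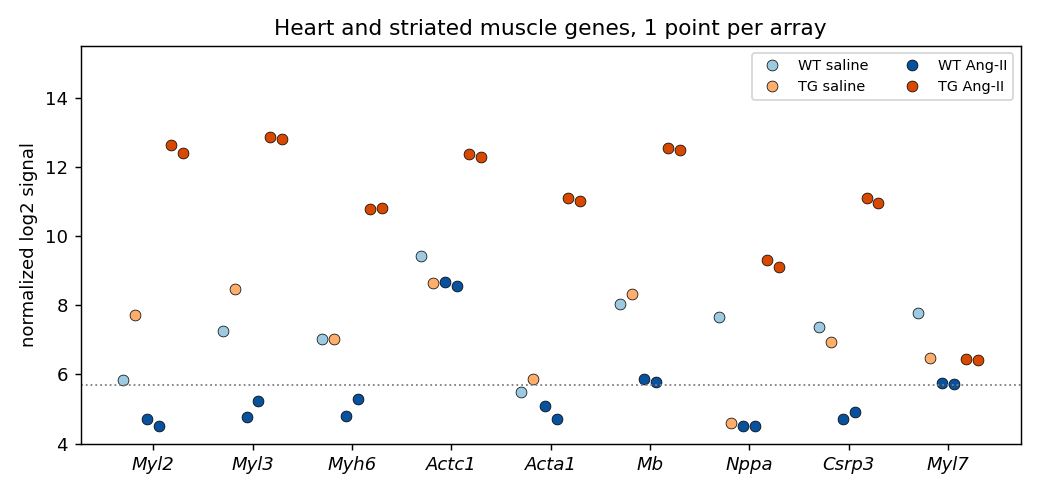
Normalized log2 signal of 9 transcripts abundant in heart muscle on each of the 6 arrays, with 1 point per array and a dotted line at 5.69, the highest over the arrays of the lowest value among detected probes. Both TG Ang-II arrays lay above every other array for Myl2 (12.5 against 7.7 at most in group mean) and Mb (12.5 against 8.3), and the WT Ang-II arrays lay lowest for Mb (5.8).

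Matrix genes as a list did not pass between TG and WT under Ang-II, and few macrophage, endothelial and fibroblast markers passed singly. Of 30 collagens and matrix proteins, 0 were higher, 1 was lower and 29 did not pass (0 higher and 1 lower when adjusted over the list alone) (camera adjusted p = 0.0949, median -0.14). Cemip, which is not a member of that list, was lower in TG (log2 -2.42 ± 0.12, adjusted p = 0.000644), with an additive adjusted p = 0.151. Of 20 macrophage and monocyte markers, 0 were higher, 4 were lower and 16 did not pass (2 higher and 5 lower when adjusted over the list alone). The macrophage median was -0.19 (camera adjusted p = 0.0127, adjusted p = 0.283 with an estimated correlation). Fcer1g, the gamma chain of Fc receptors, was lower (-1.11 ± 0.15, adjusted p = 0.0153), a call that ended without WT Ang-II array 1 (0.0798), WT Ang-II array 2 (0.100) or TG Ang-II array 1 (0.0509). Of 13 endothelial markers, 1 was higher, 0 were lower and 12 did not pass (6 higher and 0 lower when adjusted over the list alone). The endothelial median was 0.27 (camera adjusted p = 0.00138, adjusted p = 0.283 with an estimated correlation). Of 14 fibroblast markers, 1 was higher, 0 were lower and 13 did not pass (4 higher and 0 lower when adjusted over the list alone). The fibroblast median was 0.13 (camera adjusted p = 0.0234, adjusted p = 0.283 with an estimated correlation). The fibroblast call ended without WT Ang-II array 1 (adjusted p = 0.0518). Of 19 contractile genes of smooth muscle, 2 were higher, 0 were lower and 17 did not pass (5 higher and 0 lower when adjusted over the list alone). The contractile gene median was 0.15 (camera adjusted p = 0.00328, adjusted p = 0.283 with an estimated correlation). The 2 that were higher were Des, the intermediate filament protein desmin, which heart muscle also expresses (1.27 ± 0.14, adjusted p = 0.00832), and Lmod1, a leiomodin of smooth muscle (0.70 ± 0.13, adjusted p = 0.0441). Without WT Ang-II array 1 or 2 adjusted p was 0.0765 or 0.0612 for Des and 0.151 or 0.180 for Lmod1, and for Lmod1 it was 0.127 or 0.103 without TG Ang-II array 1 or 2, 0.0833 without the detection filter and 0.346 in the additive model, which gave 0.0754 for Des. Of 12 circadian clock genes, 4 were higher, 0 were lower and 8 did not pass (5 higher and 0 lower when adjusted over the list alone). The clock median was 0.45 (camera adjusted p = 0.000219, adjusted p = 0.283 with an estimated correlation). Ciart, a repressor in the clock, was higher (log2 1.93 ± 0.23, adjusted p = 0.0111) (additive adjusted p = 0.108). Of 21 respiratory chain genes, 0 were higher and 0 lower by limma (0 higher and 4 lower at an unadjusted p under 0.05), while the list passed as a whole (median -0.17, camera adjusted p = 0.0101, adjusted p = 0.283 with an estimated correlation, fry adjusted p = 0.0205), but not without TG Ang-II array 2 (adjusted p = 0.0526). Eif2s3y, a translation factor gene of the Y chromosome, was higher in TG (at least 36.6-fold, adjusted p = 0.000147). Sspn (at least 106-fold, adjusted p = 3.26e-05) and Me1 (at least 9.86-fold, adjusted p = 0.000101) were higher, with 4.4 and 4.6 as the WT Ang-II means and at least 12.0 and 8.9 as the means of the other groups. In the additive model adjusted p was 0.131 for Sspn and 0.177 for Me1. Agtr1a was higher (log2 1.19 ± 0.19, adjusted p = 0.0253), a call that ended without the detection filter (adjusted p = 0.0822), WT Ang-II array 1 (0.134), WT Ang-II array 2 (0.142) or TG Ang-II array 2 (0.0570). On these arrays the striated muscle and adipocyte lists differed by medians of 1.70 and -0.57. Over all probes 458 were higher and 427 lower in TG, 352 and 310 genes. The count of 885 calls was 1802 with quantile normalization without background correction, 1466 with an offset of 50, 1868 with a trended robust prior, 483 without the detection filter and 256 in the additive model. It was 524 and 472 without TG Ang-II array 1 and 2, and 145 and 159 without WT Ang-II array 1 and 2.

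Under saline, the lone TG array differed from the lone WT array in few single transcripts, with fat cell, red cell and endothelial markers higher as lists. Eif2s3y was higher in TG (at least 38.4-fold, adjusted p = 0.00769), and so was Cap1, a cyclase-associated actin regulator (log2 5.10 ± 0.33, adjusted p = 0.0155). Hnrnpl was lower in TG (log2 -5.09 ± 0.18, adjusted p = 0.00346) and so was Nppa (at least 4.01-fold, adjusted p = 0.0155). Of 13 endothelial markers, 0 passed by limma over all probes (8 were higher when adjusted over the list alone, 8 at an unadjusted p under 0.05). The endothelial median was 0.68 (camera adjusted p = 4.69e-06, adjusted p = 0.378 with an estimated correlation), and fry adjusted p = 0.0264. Of 14 general and 10 brown adipocyte markers and 7 erythroid markers, 0 passed by limma, and 7, 5 and 5 were higher when adjusted over the list alone (7, 5 and 5 at an unadjusted p under 0.05, where 1 brown adipocyte marker was lower). Their medians were 0.54, 0.60 and 0.83, with camera adjusted p = 0.000193, 0.00342 and 0.000173. With an estimated correlation adjusted p was 0.378, 0.378 and 0.399, and fry gave adjusted p = 0.0264, 0.0264 and 0.0431. Fibroblast markers were higher as a list (median 0.24, camera adjusted p = 0.00200, adjusted p = 0.378 with an estimated correlation, fry adjusted p = 0.0264). Of their 14 members 0 passed by limma, 5 at an unadjusted p under 0.05 and 1 when adjusted over the list alone. Respiratory chain genes were higher as a list (median 0.28, camera adjusted p = 0.000914, adjusted p = 0.378 with an estimated correlation, fry adjusted p = 0.0264), where 0 of 21 members passed by limma, 3 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Immediate-early genes were higher as a list (median 0.16, camera adjusted p = 0.0435, adjusted p = 0.399 with an estimated correlation, fry adjusted p = 0.0264), where 0 of 18 members passed by limma, 6 were higher and 1 lower at an unadjusted p under 0.05 and 2 higher when adjusted over the list alone. That call ended with probes detected on all 6 arrays (adjusted p = 0.0761), without WT Ang-II array 1 or 2 (0.0618 or 0.0624) and without TG Ang-II array 1 or 2 (0.0542 or 0.0531). It also ended without heart muscle, fat cell and red cell genes (adjusted p = 0.0669), with the same median of 0.16. CaMKII and calcium handling genes were lower as a list (median -0.24, camera adjusted p = 0.0114, adjusted p = 0.508 with an estimated correlation), while fry did not call them (adjusted p = 0.181). Of their 24 members 0 passed by limma, 7 were lower and 2 higher at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone. The calcium call ended without heart muscle, fat cell and red cell genes (adjusted p = 0.0787), with a median of -0.21. Over all probes 17 were higher and 14 lower in TG (limma, tested through the spread of the Ang-II arrays), 13 and 9 genes. The count of 31 calls was 635 with quantile normalization without background correction, 314 with an offset of 50, 735 with a trended robust prior, 147 with probes detected on all 6 arrays and 1 without the detection filter, which ended the calls of Eif2s3y (adjusted p = 0.0678), Cap1 (0.0937) and Nppa (0.0678). It was 51 without TG Ang-II array 1 and 4 each without WT Ang-II array 1 and 2, where Nppa had an adjusted p of 0.0941 and 0.0992.

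The response to Ang-II differed between genotypes most in heart muscle transcripts, many of which rose in TG and fell in WT, and in fat cell and red cell transcripts, which rose more in WT (TG response minus WT response, all 6 arrays). A positive value means a larger rise or a smaller fall in TG. Mb differed by 6.41 ± 0.22, adjusted p = 0.000974. Of 11 striated muscle markers, 7 were positive, 0 negative and 4 did not pass (8 and 1 when adjusted over the list alone). The striated muscle median was 2.23 (camera adjusted p = 1.37e-12, adjusted p = 0.221 with an estimated correlation). Of 24 CaMKII and calcium handling genes, 1 was positive and 0 negative (5 and 0 when adjusted over the list alone). The calcium median was 0.24 (camera adjusted p = 0.00242, adjusted p = 0.377 with an estimated correlation). The member that passed was Pln, which heart muscle expresses (4.16 ± 0.25, adjusted p = 0.00284). Without heart muscle, fat cell and red cell genes the call ended (adjusted p = 0.0653) with a median of 0.20. Of 19 contractile genes of smooth muscle, 0 passed by limma over all probes (5 were positive when adjusted over the list alone, 5 at an unadjusted p under 0.05). The contractile gene median was 0.34 (camera adjusted p = 3.40e-05, adjusted p = 0.221 with an estimated correlation), and fry adjusted p = 0.0253. Of 14 general adipocyte, 10 brown adipocyte and 7 erythroid markers, 2, 3 and 5 were negative and 0 positive (10, 6 and 6 negative when adjusted over the list alone, with 1 brown adipocyte marker positive). Their medians were -1.19, -1.11 and -1.69, with camera adjusted p = 1.41e-09, 3.40e-05 and 1.37e-08. With an estimated correlation adjusted p was 0.221, 0.221 and 0.275. Ucp1 differed by -2.60 ± 0.22, adjusted p = 0.0126 and Alas2, an enzyme of heme synthesis in red cell precursors, by -2.36 ± 0.22, adjusted p = 0.0180. Collagens and matrix proteins (camera adjusted p = 0.508, median -0.12) and macrophage markers (0.127, median -0.12) did not pass as lists, with 0 members called by limma, 1 and 0 positive and 0 and 2 negative at an unadjusted p under 0.05, and fry adjusted p = 0.375 and 0.104.

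**Figure D4:**
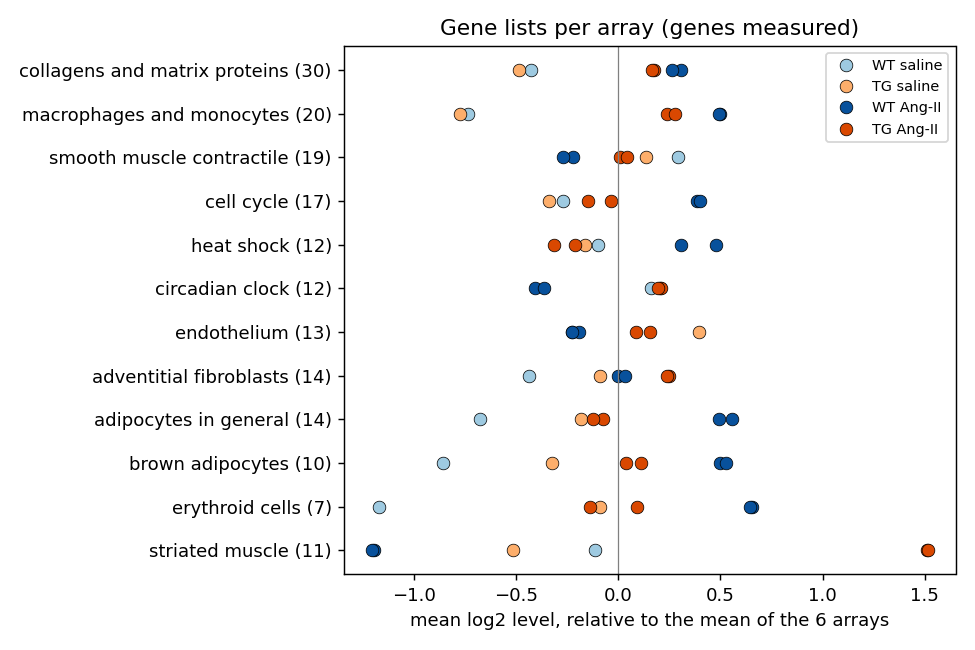
Mean log2 level of 12 gene lists on each of the 6 arrays relative to the mean over the 6 arrays, with lists on the y axis and 1 point per array, blue for WT, orange for TG and darker for Ang-II. Striated muscle markers stand highest on both TG Ang-II arrays, and adipocyte and erythroid markers stand highest on both WT Ang-II arrays, while macrophage and matrix lists are higher on all 4 Ang-II arrays than on both saline arrays.

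Other lists also differed in their response. Respiratory chain genes (median -0.50, camera adjusted p = 8.36e-06, adjusted p = 0.221 with an estimated correlation) and cell cycle genes (median -0.44, camera adjusted p = 0.00396, adjusted p = 0.275 with an estimated correlation) were negative with 0 members called by limma (6 and 7 negative at an unadjusted p under 0.05, fry adjusted p = 0.0134 and 0.0700), and the cell cycle call ended with probes detected on all 6 arrays (adjusted p = 0.122). Immediate-early genes (median -0.24, camera adjusted p = 0.00986, adjusted p = 0.293 with an estimated correlation) and heat shock genes (median -0.35, camera adjusted p = 0.00470, adjusted p = 0.377 with an estimated correlation) were negative, with 1 and 2 members called (3 and 3 when adjusted over the list alone), where Atf3 differed by -2.01 ± 0.25, adjusted p = 0.0319, and Hspa1a by -1.81 ± 0.22, adjusted p = 0.0292. Both of these calls ended without the detection filter (adjusted p = 0.0878 and 0.0639) and without TG Ang-II array 1 (0.0631 and 0.0627) or 2 (0.0647 and 0.0607). Circadian clock genes were positive (median 0.30, camera adjusted p = 0.00396, adjusted p = 0.346 with an estimated correlation), with 1 member called (3 when adjusted over the list alone), a call that ended with probes detected on all 6 arrays (adjusted p = 0.0598). Unfolded protein response genes were positive (median 0.22, camera adjusted p = 0.0459, adjusted p = 0.346 with an estimated correlation), with 1 member called (2 when adjusted over the list alone), and the list's call ended with probes averaged per gene (adjusted p = 0.0773), without WT Ang-II array 1 (0.0805), TG Ang-II array 1 (0.0609) or TG Ang-II array 2 (0.0703), and without heart muscle, fat cell and red cell genes (0.0542), where the median was the same (0.22). Endothelial markers were negative (median -0.30, camera adjusted p = 0.0328, adjusted p = 0.377 with an estimated correlation) with 0 members called by limma (3 at an unadjusted p under 0.05, fry adjusted p = 0.0724), a call that ended without WT Ang-II array 1 (adjusted p = 0.0674) or TG Ang-II array 2 (0.0892). Over all probes 119 had a positive and 80 a negative interaction by limma, 87 and 57 genes. The count of 199 calls was 728 with quantile normalization without background correction, 446 with an offset of 50, 775 with a trended robust prior, 60 without the detection filter and 92 without heart muscle, fat cell and red cell genes. It was 110 and 77 without TG Ang-II array 1 and 2, and 30 and 28 without WT Ang-II array 1 and 2, where no negative interaction was called, so that the calls of Ucp1 (adjusted p = 0.0792 and 0.0816), Alas2 (0.106 and 0.0954), Atf3 (0.125 and 0.109) and Hspa1a (0.140 and 0.141) ended. Over the 6 comparisons camera called 70 tests of the 26 lists. With an estimated correlation it called 0, where the lowest adjusted p was 0.154 and 23 tests had an unadjusted p under 0.05, and fry called 87. The estimated correlation of the contractile and cell cycle lists in WT was -0.033 and -0.055, below the preset 0.01, and neither list passed with it. Losing every call therefore does not by itself show that correlated members had made the calls.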

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

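The tests in this part were chosen after the results they examine had been seen, except that of fat cell transcripts outside the fixed lists. Each result below passed the test of the interaction, of whether the Ang-II response differs between TG and WT, by limma for genes and camera for lists: 119 probes with a positive and 80 with a negative difference. Fitted differences of genes near background in a group depend on the offset and are no bounds.

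Heart muscle transcripts stood high on both TG Ang-II arrays and low on both WT Ang-II arrays. The interaction was 7.78 for Nppa, 7.03 for Cox6a2, 6.68 for Csrp3, 6.63 for Myl3, 6.41 for Mb, 6.03 for Myl2, 5.77 for Acta1, 5.76 for Myh6, 5.34 for Tnnc1 and 5.03 for Ckmt2, and the median of the striated muscle list was 2.23 (adjusted p = 0.221 with an estimated correlation, which does not pass). A candidate explanation is heart muscle tissue in the TG Ang-II RNA pool: of 32 measured abundant heart transcripts, 26 of which were also detected on both saline arrays, 17 were neither named before nor in the striated list, and of these 64.7% (11) were called higher in TG under Ang-II and 0 lower (limma, median 1.24), against 3.02% of all genes by the same rule of 1 probe per gene, with Actn2 at 11.2 and 11.4 on the TG arrays and 9.33 and 9.35 on the WT arrays. Skeletal muscle is argued against, as 0 of 10 fast skeletal transcripts were detected on both TG Ang-II arrays and highest there, and so is background correction as the whole cause, since without it, under quantile normalization, the median difference of the striated list between TG and WT under Ang-II fell from 1.70 to 0.69 and the list still passed by camera with the preset correlation. An effect of the inhibitor peptide on these genes stays open and was not tested.

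Fat cell and red cell transcripts rose more with Ang-II in WT than in TG. The interaction had a median of -1.19 in the general adipocyte, -1.11 in the brown adipocyte and -1.69 in the erythroid list (adjusted p = 0.221, 0.221 and 0.275 with an estimated correlation, which do not pass), and was -2.77 for Slc27a2, -2.76 for Elovl6, -2.70 for Irs3, -2.66 for Slc4a1, -2.63 for Pnpla3, -2.60 for Ucp1, -2.51 for Clstn3 and -2.39 for Lncbate10, where each gene call ended without WT Ang-II array 1 or 2 (adjusted p from 0.0685 to 0.109), except Slc4a1, which was then not tested, and those of Clstn3 and Lncbate10 also without the detection filter (0.0534 and 0.0534). A test written before its result was seen asked whether the pools may hold different amounts of fat around the aorta: of 15 fat cell transcripts outside the fixed lists (15 detected on both saline arrays) 13 were negative, with a median of -1.19 and 0% of random lists as low. A smaller share of smooth muscle RNA in the WT Ang-II pool, if it were the only cause, would raise all other cell types alike. The fibroblast median exceeded the adipocyte median by 1.12 (jackknife SD 0.0963, 1.01 to 1.15 without 1 Ang-II array). That argues against such a share as the only cause. A contribution of it stays open, as the contractile list fell in WT (median -0.58). No saline array was left out, and the adipocyte median already differed by 0.54 between the lone TG and WT saline arrays. A response of fat tissue to Ang-II that depends on genotype stays open and was not tested.

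Some probes widely parted 1 genotype or 1 pool from all other arrays, among them Sspn (7.43, low only in WT Ang-II) and Hnrnpl (4.92, low only in TG saline). All 3 TG arrays differed from all 3 WT arrays by at least 1 log2 at 45 probes (30 higher in TG). The other 9 splits into 3 and 3 gave 3 at most, but are too few for a share under 0.05. Most part the 2 arrays of an Ang-II group, so are no reference. Strain variants passed on near the transgene are argued against as the source of most of the 45. Their 34 placed genes held 5 pairs within 50 genes of each other, the median of 10000 random sets (5, 95th percentile 10, permutation p = 0.629). Pools of different sex are argued against by Uty and Kdm5d, 2 Y-linked genes besides Eif2s3y with TG minus WT differences of -0.24 and -0.35. Variants under single probes in the WT Ang-II pool stay open, since of 6 genes with a second probe 50% (3: Csrp3, Mb and Tbc1d1, of which Csrp3 and Mb are heart transcripts) had another probe that was also called lower, so that neither outcome foreseen was met. For the remaining genes no other probe was called lower. Those probes gave 0.59 and 0.17 for Nnmt (-3.99 at the low probe), 0.33 for Slc15a2 (-2.38) and -0.77 for Rpl29 (-4.63). A mixed strain background was not tested and may contribute too, as genes that vary between strains, such as H2-T10 and Ifi202b, are among the 45.

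Other single genes that differed were Saa3 (-3.11), Hs6st2 (-2.39), Cemip (-2.38) and Dusp4 (-2.36). Each of these calls ended without WT Ang-II array 1 or 2 (adjusted p = 0.0525 and 0.0685, 0.0815 and 0.109, 0.101 and 0.0940, and 0.106 and 0.0934), and all but that of Cemip without the detection filter (0.0534, 0.0960 and 0.0601). That of Hs6st2 also ended without TG Ang-II array 1 or 2 (0.0557 and 0.0607), and another probe of Dusp4, at -1.77, did not pass (0.115). Other lists that differed had medians of 0.34 (smooth muscle contractile), -0.24 (immediate-early), 0.24 (CaMKII and calcium handling), -0.44 (cell cycle), 0.22 (unfolded protein response), -0.50 (respiratory chain), 0.30 (circadian clock), -0.35 (heat shock) and -0.30 (endothelium). None of these lists passed with an estimated correlation (adjusted p from 0.221 to 0.377), and the calcium handling and unfolded protein calls also ended without heart muscle, fat cell and red cell genes (0.0653 and 0.0542, medians 0.20 and 0.22).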

How the results depend on the processing

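The refit without heart muscle, fat cell and red cell genes was chosen after seeing the data. It lowered the interaction calls from 199 to 92 and the called list tests from 70 to 45, in part because it removes 4 of the lists. Camera with an estimated correlation called 0 list tests (23 at an unadjusted p under 0.05, and 87 by fry). It also missed the shift put into simulated genes that varied independently. In the other settings between 60 and 76 list tests were called.

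The counts of calls depended on normalization and prior. In WT, TG, TG against WT under Ang-II, saline and the interaction, they were 2931, 2233, 1802, 635 and 728 with quantile normalization without background correction, and 3015, 2303, 1868, 735 and 775 with a trended robust prior. An offset of 50 gave 2323 (WT), 1466 (TG against WT under Ang-II), 314 (saline) and 446 (interaction). The cause was not tested. Without the detection filter, when p-values are adjusted over all probes, the 6 counts were 781, 604, 2106 (average), 483, 1 and 60. Detection on all 6 arrays gave 147 under saline, and probes averaged per gene gave 754 in TG and 2113 in the average. An additive model gave 1838 in the average and 256 between genotypes. The slope of 0.96 was 0.87 with detection on all 6 arrays and 0.88 with probes averaged per gene.

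Leaving out 1 Ang-II array at a time gave 209 to 1666 calls in WT, 639 to 794 in TG, 1555 to 2832 in the average, 145 to 524 between genotypes under Ang-II, 4 to 51 under saline and 28 to 110 in the interaction, slopes of 0.92 to 1.02, and 67 to 71 called list tests. The lone array left in a group is assumed to vary like the other groups, and 1 residual degree of freedom is lost. With Ang-II array numbers as a replicate block, saline calls fell from 31 to 20. That block and array weights moved no other count by over 1.5 times. The numbers are not taken to pair the arrays (2 pairs, correlation 0.12 between deviations of same-numbered arrays). The deposited table (the same values) and the 4 Ang-II arrays alone (the same residuals) could move no count.

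Other probes of a named gene had the opposite sign for Atp2c1 (0.30), Slc15a2 (0.33) and Camk2d (0.97, adjusted p = 0.0426) in WT and Camk2d (0.62, adjusted p = 0.0351) in the average, Pcnp in TG (0.92) and the average (0.67), Lrp6 (0.39) and Mbp (-0.39) between genotypes under Ang-II, Sox9 in WT (-0.80) and the average (-0.49), Serpinf1 in WT (-0.063), Ncam1 in TG (-0.15 and -0.13) and Hspa1b in the average (-0.042). With detection on all 6 arrays the medians of the cell cycle and striated muscle lists in the average were -0.11 and -0.17. Of the results of named genes over all settings, 6854 stayed called in the same direction or stayed without a call, 706 lost the call, 238 gained it and 14 reversed. For lists these numbers were 1682, 99, 29 and 2. Signal over background limits what can be said of genes that one group does not express well, whose folds are lower bounds.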

Other observations

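The lists in this part were chosen after seeing the data, and its single genes come from the rule for named genes unless stated. Chad, which encodes chondroadherin, was higher in TG under saline (log2 2.28 ± 0.20, adjusted p = 0.0335) and under Ang-II (log2 2.96 ± 0.14, adjusted p = 0.000551), and Acan, which encodes aggrecan, was lower (at least 2.35-fold, adjusted p = 0.0335 under saline, at least 2.67-fold, adjusted p = 0.00297 under Ang-II). Both are among the genes of the 45 probes that parted the genotypes, for which a mixed strain background stays open. Ccn1, a matrix-associated protein that is induced by growth factors and mechanical strain, fell with Ang-II in TG (-1.30 ± 0.17, adjusted p = 0.0144) and was lower in TG than WT under Ang-II (-1.72 ± 0.14, adjusted p = 0.00360), while its interaction did not pass (-1.57 ± 0.24, adjusted p = 0.0576) but did with quantile normalization without background correction (0.000267), an offset of 50 (0.00758), detection on all 6 arrays (0.0254), probes averaged per gene (0.0318) and a trended robust prior (4.72e-05). Agtr1a was also higher in TG under saline by 1.71 ± 0.26, adjusted p = 0.0869, which did not pass. That difference was 0.97 and passed with quantile normalization without background correction (adjusted p = 0.00443), and passed with an offset of 50 (0.0196), detection on all 6 arrays (0.0388) and a trended robust prior (0.00202). Its response did not pass in WT (0.54 ± 0.23, adjusted p = 0.194) or TG (0.02 ± 0.23, adjusted p = 0.961). Saa3, an acute-phase protein, was above background in TG saline (7.14) and WT Ang-II (6.17), and not well above it in the other groups. In the saline comparison the calls of Chad and Acan ended without the detection filter (adjusted p = 0.107 and 0.107) and without WT Ang-II array 1 or 2 (0.102 or 0.107 and 0.119 or 0.123). Both also ended with a replicate block (0.0553 and 0.0553), and another probe of Acan, at -1.63, did not pass (0.0649).

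Of 8 transcripts of proteins secreted by liver, 4 fell with Ang-II in WT and 5 in TG, 0 rose, and the medians were -1.27 and -1.31 (camera adjusted p = 0.0441 in WT and 0.0534 in TG over 3 lists in 6 comparisons, 0.376 in each with an estimated correlation). Most of those that fell are Serpina1 paralogs, so near in sequence that their probes are not taken as independent. Of 12 complement genes 3 rose in WT, where C4b rose by 1.13 ± 0.17 (adjusted p = 0.0166), and the list did not pass (median 0.38, camera adjusted p = 0.0534). In TG 2 rose and 1 fell, with a median of 0.32. There C4b rose by 1.28 and Cfi by 1.29, while C7 fell by 1.55 (limma adjusted p = 0.00936). The list of 11 secreted Wnt regulators had a median of 0.23 in TG (camera adjusted p = 0.0441, 0.376 with an estimated correlation), where 0 members rose and 0 fell by limma (3 rose and 0 fell at an unadjusted p under 0.05).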
